A study of Astyanax mexicanus with 26 samples.

How the data were processed

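Adult livers of surface, Pachón cave and Tinaja cave *Astyanax mexicanus* were profiled by chromatin immunoprecipitation of H3K4me3, H3K27ac and H3K27me3 followed by single-read Illumina sequencing, per the labels. The series held 26 libraries, of which 20 were immunoprecipitates and 6 were total chromatin, the background named for each immunoprecipitate in the labels. The submitters' processing notes name bcl2fastq 2.20, Bowtie2, SAMtools and MACS2. The settings, the remaining versions, the genome build and the way replicates were combined are not given in the sources used here.

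The authors deposited 1 peak list per morph and mark, 9 in all, giving the position of each peak. The deposited score is 0 for every peak, and no height, fold enrichment or significance is given, so peaks were ranked by width where a ranking was needed. Neither reads nor total chromatin libraries were analysed here. The depth behind each list is unknown, and differences in depth, enrichment, antibody performance or number of pooled libraries would change which weak peaks are listed. Absence of a peak means absence from a list, not absence of the mark.

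The lists named 25 placed chromosomes and 2103 unplaced scaffolds, with last peak ends summing to 1310 Mb, or 930 Mb on the placed chromosomes. The gene table at hand is of the assembly AstMex3_surface. Its coordinates did not match those of the lists: on chromosome 1 the last peak ended at 27.0 Mb and the last gene at 134 Mb. Coordinates are those of the lists, counted from 1, in a build not given in the sources used here. Planned results that needed start sites or gene names, among them promoter marks, gene lists and distal H3K27ac, were not run, and regions carrying marks took their place. The rule for naming genes, the planned comparisons and a first set of alternative settings were fixed before the data were examined, and later settings are named as such. Not in the plan were, among others, the expectation from list length and H3K27me3 at the classes of regions. The widest H3K27me3 domains and their coincidence with H3K4me3 domains were not in it either. As no gene could be named, regions were named by a rule chosen after the lists were seen. Up to 4 placed domains per mark were taken from those among the 20 widest of every morph, ranked by width in surface, and text examples came from the 4 placed 100 kb windows per mark and class with the largest excess of a class over its genome share.

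Overlap meant 1 bp or more. Overlap of marks within a morph was computed on placed chromosomes and set beside 100 circular shifts of the second list, each with 1 random offset per chromosome. Overlapping or touching peaks of the 3 morphs were merged into regions, which fell into 7 classes by the morphs with a peak. The number of regions expected in a class of 2 morphs was taken from a model in which a region has the same strength in every morph and each list has its own threshold on a logistic scale. The classes of 2 morphs then share out their total in inverse proportion to the number of regions found only in the morph each leaves out. The count expected for independent lists was computed in 1 kb windows. For 2 marks, regions of the first in the pair class or the single class of a split were counted by overlap with regions of the second in either class, and the odds ratio was given with a normal 95% interval on the log scale. Neighbouring regions are not independent, so these intervals are too narrow as statements about the genome. No test between morphs was made and no p-values are given, since 1 pooled list per group has no replicates and regions are not replicates.

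Alternatives were the wider 50% of each list, lists cut to the length of the shortest of their mark by width, overlap of 50% of the shorter interval, merging of peaks up to 1 kb apart, placed chromosomes only and domains without joining. Fixed 1 kb windows, the removal of peaks at the 100 widest H3K4me3 and H3K27me3 domains, comparison within 10 bins of region width and equal lists at shared H3K27me3 regions and (with bins of width) in the comparison of the cave pair with single caves, and distinct loci of coincident domains, were added after the data were seen. The interval arithmetic was tested on simulated data against base by base counting, with 0 mismatches. The expectation from list length was computed on simulated data of 300000 candidate regions. These were drawn from the same logistic model, so they check the computation and not whether real lists follow the model. Over 20 simulated sets without a difference between morphs, the ratio for the cave pair ran from 0.99 to 1.01 with unequal and from 0.98 to 1.02 with equal lists. With 10% of the regions raised in both caves it ran from 1.04 to 1.06 with unequal and from 1.08 to 1.11 with equal lists. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.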

Results

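Chromatin of adult livers was profiled by immunoprecipitation and sequencing in 3 morphs of the Mexican tetra, *Astyanax mexicanus*: the river-dwelling surface fish and the cave fish of the Pachón and Tinaja caves. The 3 marks were H3K4me3, typical of active promoters, H3K27ac, typical of active promoters and enhancers, and H3K27me3, the mark laid down by Polycomb repressive complexes. Each morph and mark had 2 libraries, except H3K4me3 and H3K27ac in Tinaja, which had 3, and each had 1 deposited peak list. Replicates were therefore pooled, and no difference between morphs could be set against a spread between replicates. Read depths are unknown from the lists, so list length is not a measure of the amount of a mark. Exact binomial intervals are given at 95% and cover counting error only.

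The lists of the active marks differed in length between morphs, and those of H3K27me3 hardly did. H3K4me3 had 56323 peaks in surface, 64432 in Pachón and 136219 in Tinaja, covering 34.0, 43.0 and 76.0 Mb. H3K27ac had 70089, 93527 and 117125 peaks in the same order, covering 43.7, 54.3 and 67.4 Mb. H3K27me3 had 97948, 98198 and 99370 peaks, covering 51.6, 52.6 and 52.9 Mb. The longest list exceeded the shortest by a factor of 2.42 for H3K4me3, 1.67 for H3K27ac and 1.01 for H3K27me3. Whether the H3K27me3 lists were made in the same way as the others is not given in the sources used here, so their even lengths are not a measure of even marking. Median peak widths were 494, 519 and 427 bp for H3K4me3, 511, 474 and 459 bp for H3K27ac, and 410, 411 and 415 bp for H3K27me3. Between 67.6% and 75.8% of the peaks of a list lay on the 25 placed chromosomes. All 3 morphs had H3K27me3 libraries of one library number, 2399. For the active marks the numbers went with the morph, except that 1934 occurred in both Pachón and Tinaja, so library number and surface against cave cannot be told apart for these marks.

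**Figure D1:**
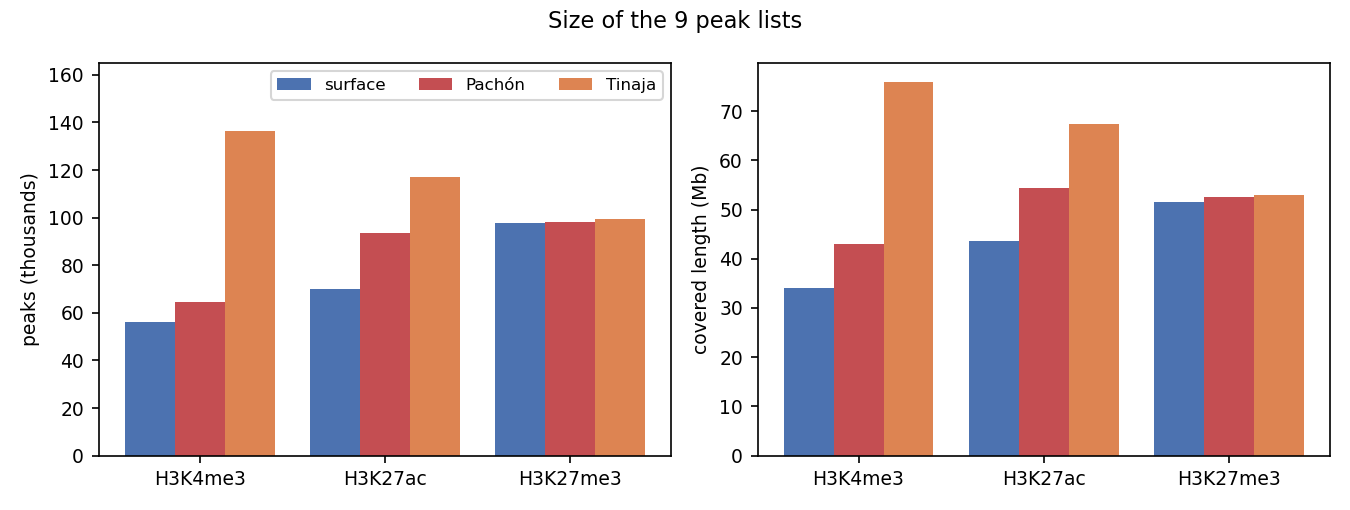
Number of peaks (left, in units of 1000) and covered length (right, Mb) of the 9 lists, with bars for surface, Pachón and Tinaja under each mark. H3K4me3 rises from 56323 peaks in surface to 136219 in Tinaja, while the 3 H3K27me3 lists lie between 97948 and 99370.

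Within each morph, the larger part of H3K4me3 lay on H3K27ac, and H3K4me3 met H3K27me3 more often than H3K27ac did. On the placed chromosomes, 52.1% of H3K4me3 peaks in surface overlapped an H3K27ac peak (95% interval 51.6 to 52.5), against 53.5% in Pachón and 52.8% in Tinaja. H3K4me3 overlapped H3K27me3 at 32.3% of peaks in surface (31.8 to 32.8), 37.4% in Pachón (36.9 to 37.8) and 36.2% in Tinaja (35.9 to 36.5). H3K27ac overlapped H3K27me3 at 10.96% of peaks in surface (10.7 to 11.2), 14.5% in Pachón (14.3 to 14.8) and 21.6% in Tinaja (21.3 to 21.9). Lists shifted along their chromosomes gave the overlap of unrelated positions. H3K4me3 met H3K27ac 7.83, 6.04 and 5.22 times as often as shifted lists did in surface, Pachón and Tinaja. H3K4me3 met H3K27me3 4.03, 4.48 and 4.62 times as often, and H3K27ac met H3K27me3 1.35, 1.85 and 2.70 times as often. Every observed share lay above the highest of the 100 shifts. The shares are of peaks, and a longer partner list raises them. It also raises the shifted share, which was 6.65%, 8.86% and 10.1% for H3K4me3 on H3K27ac, and so limits the fold. With lists of equal length the mean fold of H3K4me3 on H3K27ac was 7.29 (1 SD over morphs, 6.83 to 7.74). With the full lists it was 6.36 (5.03 to 7.70). The fall from surface to Tinaja is thus not a ranking of the morphs.

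When the 3 marks of a morph were merged into joint regions, the combination of H3K4me3 and H3K27ac without H3K27me3 held 22465 regions in surface, 24151 in Pachón and 47967 in Tinaja. H3K4me3 with H3K27me3 and no H3K27ac held 13594, 16786 and 29559 regions. This combination is known as bivalent where both marks lie together in the same cells, which pooled lists of livers cannot show. Marks of a joint region need not overlap each other, since peaks were merged in chains. All 3 marks were present in 4324 joint regions in surface, 7223 in Pachón and 20262 in Tinaja, or 2.51%, 3.82% and 9.08% of them. H3K27me3 alone held 75684, 65834 and 43107 regions. This fall and the rise in regions with all 3 marks follow the order of H3K4me3 and H3K27ac list length. Joint regions were not formed with lists of equal length, so these counts do not measure a difference between morphs. H3K27ac peaks without an H3K4me3 peak of the same morph, a mark pattern found at enhancers, numbered 42891 in surface (61.2% of H3K27ac peaks), 61506 in Pachón (65.8%) and 46928 in Tinaja (40.1%). With lists of equal length these peaks numbered 42891, 42911 and 36897 in surface, Pachón and Tinaja. That cut removes narrower peaks from the cave lists and leaves the surface lists of these marks whole. With the same share of wider peaks kept from every list, they numbered 20106, 29605 and 24509. Pachón then stood highest and Tinaja above surface, so the order of the morphs depended on the cut. H3K4me3 peaks with H3K27me3 numbered 19507, 25686 and 51589. The Tinaja number was 24376 when the H3K4me3 lists were cut to equal length by peak width.

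Across morphs, with the full lists, regions with a mark in all 3 morphs were the largest class for H3K27ac and H3K27me3. For H3K4me3 the largest class was regions of Tinaja alone. Overlapping peaks of the 3 morphs merged into 148050 H3K4me3, 140810 H3K27ac and 146107 H3K27me3 regions. A peak in all 3 morphs was present at 35695 H3K4me3 regions (24.1%), 50090 H3K27ac regions (35.6%) and 51919 H3K27me3 regions (35.5%). Tinaja alone held 70940 H3K4me3 regions (47.9%), against 5752 in surface alone and 6387 in Pachón alone. With lists of equal length Tinaja alone held 13507 H3K4me3 regions, fewer than the 29194 of all 3 morphs. For H3K27ac, 37981 regions were in Tinaja alone, 13465 in Pachón alone and 7659 in surface alone. H3K27me3 was even, with 20057 regions in surface alone, 17625 in Pachón alone and 19043 in Tinaja alone. In surface, 89.8% of H3K4me3 peaks, 89.1% of H3K27ac peaks and 79.5% of H3K27me3 peaks met a peak of another morph. In Tinaja these shares were 47.9%, 67.6% and 80.8%.

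**Figure D2:**
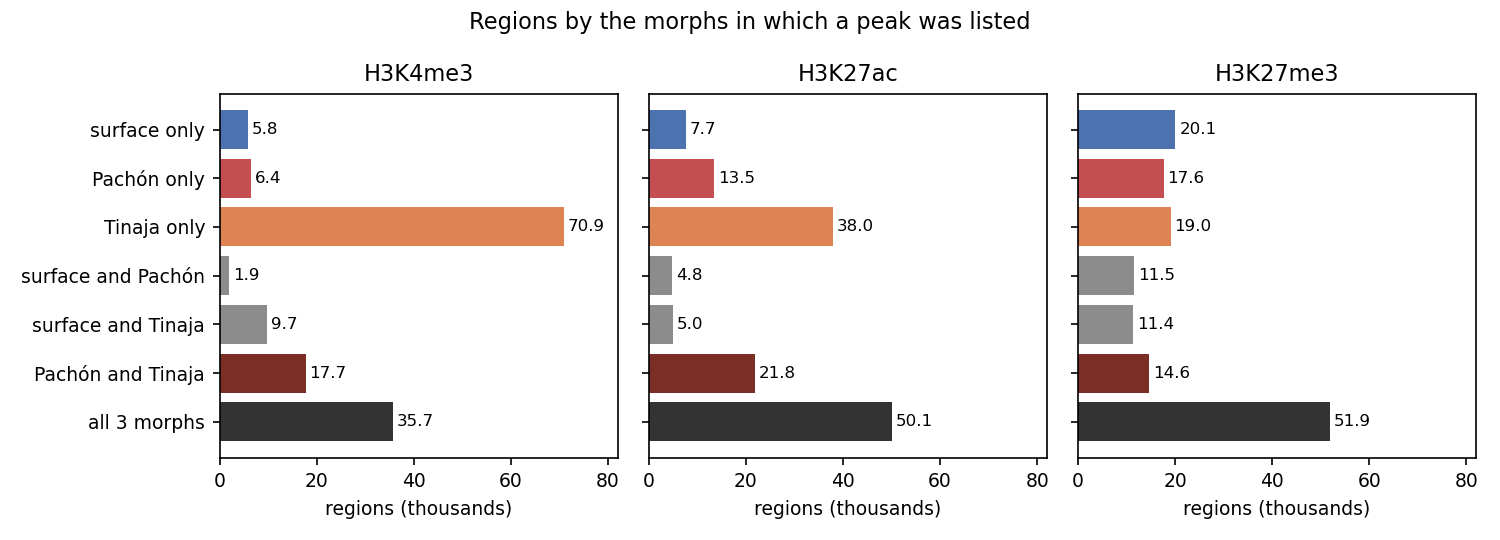
Number of regions (horizontal axis, in units of 1000) in each of the 7 combinations of morphs with a peak, 1 panel per mark. Regions of all 3 morphs number 35695 for H3K4me3, 50090 for H3K27ac and 51919 for H3K27me3, and Tinaja alone holds 70940 for H3K4me3.

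The contrast of the cave morphs with surface fish rests on regions with a peak in both caves and none in surface. There were 17690 such regions for H3K4me3, 21846 for H3K27ac and 14575 for H3K27me3, and in each mark this was the largest of the 3 classes with a peak in exactly 2 morphs. Surface and Pachón without Tinaja shared 1879, 4817 and 11483 regions, and surface and Tinaja without Pachón shared 9707, 4952 and 11405. Because a longer list joins more classes, each class was set beside the number expected from list length if all morphs had the same regions. The cave pair exceeded that number by a factor of 1.197 for H3K4me3, 1.22 for H3K27ac and 1.24 for H3K27me3. The pair of surface and Pachón stood at 1.57, 1.34 and 0.93, and that of surface and Tinaja at 0.73, 0.49 and 0.85. The 3 expected numbers add up to the observed total, so a deficit in one pair comes with an excess in another. With the full lists the cave pair was the highest of the 3 pairs for H3K27me3 alone. With lists of equal length it was the highest for all 3 marks, at 1.36, 1.59 and 1.25, against 1.12, 1.202 and 0.92 for surface and Pachón. Surface and Pachón stayed above the cave pair for H3K4me3 in the wider 50% of each list (1.68 against 1.16) and on placed chromosomes (1.64 against 1.24), and for H3K27ac on placed chromosomes (1.28 against 1.24). For H3K27ac in the wider 50% the cave pair was the higher (1.21 against 1.03). With lists of equal length the cave pair held 8043 H3K4me3 and 9477 H3K27ac regions, and on placed chromosomes 11692 H3K4me3 regions of the full lists. In 1 kb windows lacking the mark in the remaining morph, every pair of morphs shared a mark more often than independent lists would. The factors for H3K4me3, H3K27ac and H3K27me3 were 7.70, 9.16 and 11.8 for the cave pair, 29.0, 18.03 and 11.2 for surface and Pachón, and 7.11, 8.50 and 10.6 for surface and Tinaja. These factors are capped by the length of the longer list, so they do not rank the pairs.

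In some chromosomal stretches these regions made up a far higher share than in the genome. On chromosome 5, from 32600001 to 32700000, 18 of 29 H3K27ac regions had peaks in both caves and not in surface, against 15.5% of H3K27ac regions in the genome, while 0 of its 10 H3K4me3 regions were of that class. On chromosome 20, from 7500001 to 7600000, the number was 20 of 35, with 4 of 29 H3K4me3 regions, a share near that of the genome. On chromosome 13, from 30100001 to 30200000, it was 12 of 17, with 5 of 11 H3K4me3 regions. For H3K4me3, 9 of 13 regions on chromosome 7 from 21700001 to 21800000 and 10 of 17 on chromosome 18 from 11400001 to 11500000 were of the cave pair, against 11.9% overall. For H3K27me3, 8 of 16 regions on chromosome 8 from 19200001 to 19300000 were of the cave pair, against 9.98% overall. The share of the cave pair varied little between whole chromosomes, from 12.5% on chromosome 11 to 17.8% on chromosome 18 for H3K27ac and from 8.45% on chromosome 5 to 10.97% on chromosome 12 for H3K27me3.

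Other stretches carried a mark in surface fish alone. Adjoining windows of chromosome 18, from 16000001 to 16100000 and from 16100001 to 16200000, held H3K27me3 in surface alone at 13 of 19 and 14 of 18 regions, against 13.7% overall. The same 2 windows each held 43 H3K4me3 regions, of which 1 was in surface alone, and 24 and 38 H3K27ac regions, of which 0 were. This does not show active marks shared by the morphs. In the window from 16100001 most peaks of both active marks were of Tinaja. Surface alone also held few regions of these marks in the genome, 3.89% for H3K4me3 and 5.44% for H3K27ac. A window on chromosome 1, from 16100001 to 16200000, had 8 of 9 H3K27me3 regions in surface alone. For H3K27ac, surface alone held 13 of 24 regions on chromosome 17 from 6800001 to 6900000 and 10 of 18 on chromosome 19 from 11000001 to 11100000, against 5.44% overall. On chromosome 24, from 44500001 to 44600000, surface alone held 7 of 10 H3K27ac regions and 13 of 23 H3K27me3 regions. For H3K4me3, surface alone held 5 of 9 regions on chromosome 15 from 19900001 to 20000000, against 3.89% overall. The windows were those furthest above the genome share and give no test.

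H3K27me3 was frequent at the H3K4me3 and H3K27ac regions that the cave morphs shared. Of the 17690 H3K4me3 regions of the cave pair, 50.5% overlapped an H3K27me3 peak of surface fish (95% interval 49.7 to 51.2), against 35.1% of the regions of all 3 morphs (34.6 to 35.6). For H3K27ac the shares were 28.1% (27.5 to 28.7) and 12.8% (12.5 to 13.1). Regions of Tinaja alone met surface H3K27me3 at 34.3% for H3K4me3 and 35.2% for H3K27ac, and regions of Pachón alone at 24.0% and 14.3%. Regions of surface alone did so at 28.4% for H3K4me3 and 7.53% for H3K27ac. The H3K27me3 lists of the caves gave 54.8% (Pachón) and 54.5% (Tinaja) at H3K4me3 regions of the cave pair, and 27.2% and 28.4% at H3K27ac regions. Where an H3K4me3 region of the cave pair met H3K27me3 in any morph, 67.0% met it in all 3 morphs, and for H3K27ac 48.8% did. These shares were not above those of regions of all 3 morphs, 72.1% and 49.3%. The latter regions were wider, with medians of 822 and 748 bp against 523 and 466 bp, and width was not matched here. Regions of Tinaja alone gave 46.0% for H3K4me3 and 58.2% for H3K27ac, and those of Pachón alone 32.7% and 40.8%. With lists of equal length the ratio of the cave pair to all 3 morphs was 1.75 for H3K4me3 and 2.69 for H3K27ac, against 1.44 and 2.19 with the full lists.

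**Figure D3:**
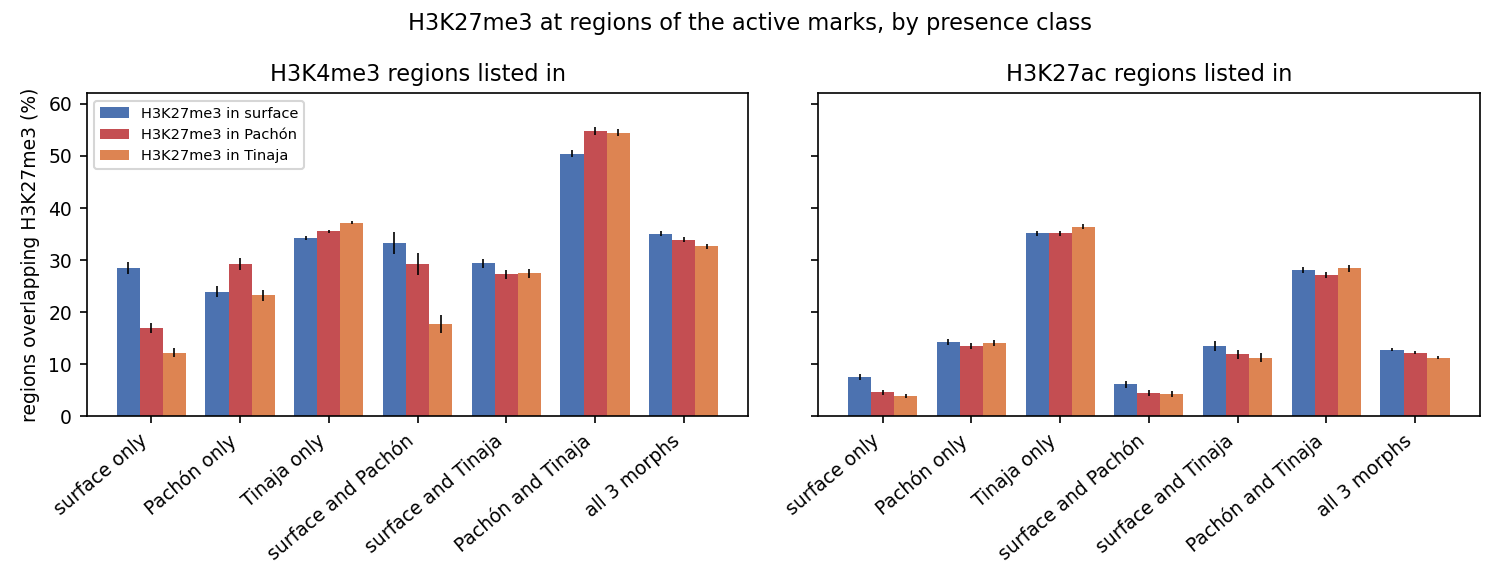
Percentage of H3K4me3 regions (left) and H3K27ac regions (right) that overlap an H3K27me3 peak of surface, Pachón or Tinaja, for each combination of morphs with a peak, with exact 95% binomial intervals. For surface H3K27me3, the cave pair reaches 50.5% for H3K4me3 and 28.1% for H3K27ac, and regions of all 3 morphs 35.1% and 12.8%.

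Where 2 marks differed between the cave pair and surface at the same place, they differed in the same direction more often than independent marks would, active and repressive marks included. H3K4me3 and H3K27ac gave 2461 H3K4me3 regions with both marks in the caves alone and 558 with both in surface alone, against 50 and 100 in opposite directions. Their odds ratio was 275 (95% interval 193 to 390). H3K4me3 and H3K27me3 gave 1252 and 718 regions in the same direction and 534 and 73 in opposite directions, an odds ratio of 23.1 (17.8 to 29.9). H3K27ac and H3K27me3 gave 772 and 286 in the same direction and 886 and 29 in opposite directions, an odds ratio of 8.59 (5.80 to 12.7). The 886 were H3K27ac regions of the cave pair with H3K27me3 in surface alone and outnumbered the 772 with H3K27me3 in the cave pair, so the odds ratio rests on surface-alone H3K27ac, where 286 stood against 29. H3K4me3 and H3K27ac shared library numbers within each morph, and H3K27me3 shared none with them. The other splits of 2 morphs against 1 gave 1974 and 161 for H3K4me3 with H3K27ac and 9.03 and 3.64 for H3K4me3 with H3K27me3, for Tinaja and Pachón as the single morph. For H3K27ac with H3K27me3 they gave 1.35 (0.86 to 2.12) and 0.70 (0.49 to 1.00). With lists of equal length the cave against surface odds ratio was 13.3 for H3K4me3 with H3K27me3 and 5.51 for H3K27ac with H3K27me3. With the wider 50% of each list it was 532 for H3K4me3 with H3K27ac and 4.76 for H3K27ac with H3K27me3.

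**Figure D4:**
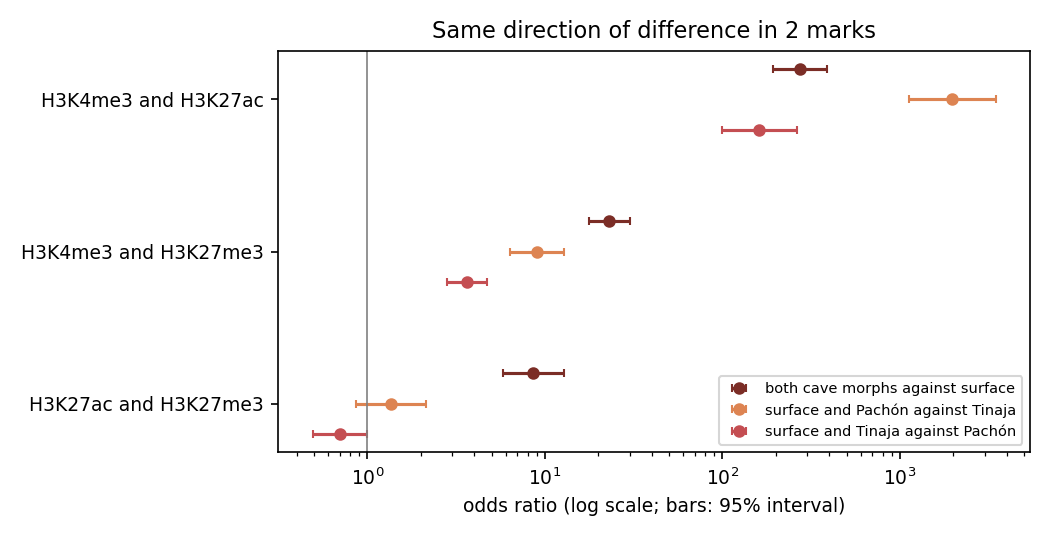
Odds ratio (log axis, with 95% intervals) that 2 marks differing between morphs at one place differ in the same direction, for both caves against surface, surface and Pachón against Tinaja, and surface and Tinaja against Pachón. For H3K27ac and H3K27me3 the first is 8.59 and the others are 1.35 and 0.70.

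The widest H3K27ac domains lay outside H3K27me3. Of the 100 widest per morph, after peaks at most 1 kb apart were joined, 86 in surface, 89 in Pachón and 84 in Tinaja were on placed chromosomes, and H3K27me3 covered 1.46%, 2.24% and 2.83% of their length. In each morph, 34 of them were among the widest of all 3. A domain on chromosome 20, between 1796384 and 1820435, summed to 19.6 kb in surface, 22.9 kb in Pachón and 18.4 kb in Tinaja. One on chromosome 6, between 12909044 and 12930052, measured 19.5, 21.0 and 18.7 kb. Domains on chromosome 1, between 15897453 and 15914207, and on chromosome 25, between 45347018 and 45363154, measured 16.0 to 16.7 kb and 16.1 kb. None of these 4 domains carried an H3K27me3 peak in any morph, and H3K4me3 covered 16.8% to 38.5% of them.

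The widest H3K4me3 and H3K27me3 domains often coincided. Of the 100 widest H3K4me3 domains, 20 in surface, 34 in Pachón and 26 in Tinaja met one of the 100 widest H3K27me3 domains of that morph, against 13, 5 and 9 that met one of the widest H3K27ac domains. Without joining neighbouring peaks the numbers with H3K27me3 were 43, 53 and 64. On chromosome 15, between 21007692 and 21019118, H3K4me3 covered 89.6%, 87.9% and 84.1% in surface, Pachón and Tinaja, and H3K27me3 covered 86.0%, 87.9% and 93.0%. On chromosome 23, between 2509752 and 2522490, H3K4me3 covered 85.8%, 94.6% and 93.9% and H3K27me3 80.3%, 70.0% and 56.4%. On chromosome 3, between 53622740 and 53640971, H3K27me3 covered 67.0%, 72.6% and 68.4%, while H3K4me3 covered 30.1% in surface, 79.8% in Pachón and 71.3% in Tinaja. On chromosome 7, between 30798865 and 30809193, H3K27me3 covered 87.0% to 92.9%, and H3K4me3 covered 61.7% in surface, 91.5% in Pachón and 92.5% in Tinaja. H3K27ac covered 31.4% of the chromosome 7 domain in Tinaja and 0% in surface and Pachón. Fewer of these domains were on placed chromosomes than of H3K27ac, 40 to 59 of 100 for H3K4me3 and 41 to 49 for H3K27me3.

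**Figure D5:**
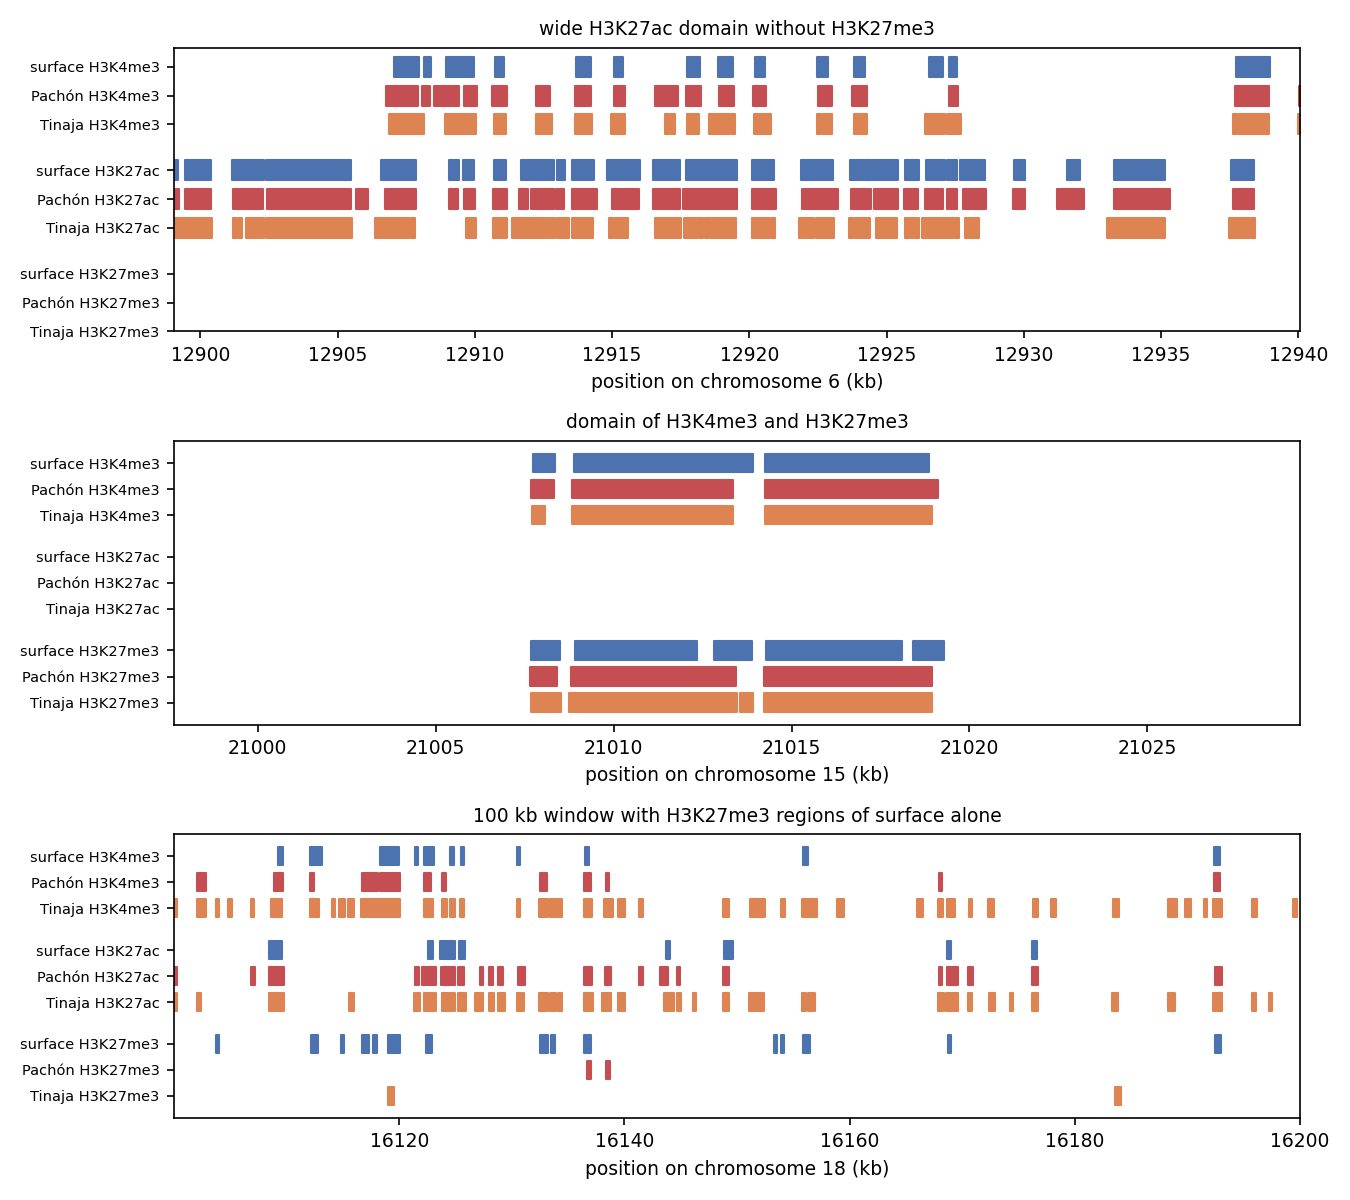
Peaks (bars) of the 3 marks in surface, Pachón and Tinaja along 3 stretches, with position in kb on the horizontal axis: a wide H3K27ac domain of chromosome 6, a domain of chromosome 15, and the window of chromosome 18 from 16100001 to 16200000. The chromosome 6 domain has 0 H3K27me3 peaks, the chromosome 15 domain has H3K4me3 and H3K27me3 over the same extent, and 14 of the 18 H3K27me3 regions of the chromosome 18 window are in surface alone.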

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

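Fixed 1 kb windows, removal of the widest domains, and placed chromosomes for odds ratios and H3K27me3 ratios were chosen after the data were seen. Of 101 values under an alternative, 51 stayed within the stated margin (a factor of 1.5 for counts, otherwise the counting interval or the SD over morphs), 50 moved and 0 of the ratios crossed 1. Counts have no direction of their own, but some orders turned with lists of equal length. H3K4me3 regions of Tinaja alone fell below those of all 3 morphs (13507 against 29194). Tinaja fell below surface in H3K27ac peaks without H3K4me3 (36897 against 42891), but not with the wider 50% of each list (24509 against 20106). The cave pair rose above surface and Pachón relative to expectation (1.36 against 1.12 for H3K4me3, 1.59 against 1.202 for H3K27ac). For H3K27ac it also did so with the wider 50% (1.21 against 1.03). No paired analysis was possible because each list pools its libraries, and for the same reason no replicate was left out. Overlap of 50% of the shorter interval was not run between morphs, where merged regions meet it by construction. Alternatives on start sites and gene lists were not run. Rankings by width stand in for significance, and depth is unknown. Except for counts, which fall by construction where peaks are removed, the cause was not tested.

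With the wider 50% of each list, H3K4me3, H3K27ac and H3K27me3 regions of the cave pair numbered 8150, 10777 and 6824, and regions of all 3 morphs 20006, 26919 and 27530. H3K27ac peaks without H3K4me3 numbered 20106, 29605 and 24509 in surface, Pachón and Tinaja, and H3K4me3 peaks with H3K27me3 9508, 12952 and 25503. The cave pair over its expectation was 1.16 for H3K4me3 and 1.29 for H3K27me3. The mean fold over shifted lists was 9.38 for H3K4me3 on H3K27ac and 6.22 on H3K27me3. Odds ratios of cave against surface were 532, 30.4 and 4.76 for H3K4me3 with H3K27ac, H3K4me3 with H3K27me3 and H3K27ac with H3K27me3. The ratio of H3K27me3 shares, cave pair to all 3 morphs, was 1.75 for H3K4me3 and 2.56 for H3K27ac.

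With lists of equal length, the cave pair held 8043 H3K4me3 and 9477 H3K27ac regions, 1.36 and 1.59 times the expectation. H3K4me3 peaks with H3K27me3 in Tinaja numbered 24376. The odds ratios with H3K27me3 were 13.3 for H3K4me3 and 5.51 for H3K27ac, and the ratios of H3K27me3 shares 1.75 and 2.69.

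With overlap of 50% of the shorter interval, the mean fold was 9.36 for H3K4me3 on H3K27ac, 6.47 on H3K27me3 and 2.89 for H3K27ac on H3K27me3. With peaks up to 1 kb apart merged, the cave pair stood at 1.25, 1.18 and 1.22 times its expectation for H3K4me3, H3K27ac and H3K27me3, and on placed chromosomes at 1.24, 1.24 and 1.22. Placed chromosomes held 11692 H3K4me3 regions of the cave pair, and the ratio of H3K27me3 shares there was 1.49. In 1 kb windows, H3K4me3 of the cave pair numbered 28588, windows of all 3 morphs 59646, 79615 and 80726, and the cave pair stood at 1.24 for H3K4me3 and 1.21 for H3K27ac. Without joining peaks, 43, 53 and 64 of the widest H3K4me3 domains met one of H3K27me3 in surface, Pachón and Tinaja.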

Other observations

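The tests of a difference shared by the cave morphs, of missing sequence as the whole cause, of the position of coincident domains and of equal lists at shared H3K27me3 regions were chosen after the result was seen.

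Regions with H3K27me3 in all 3 morphs were listed with active marks to different extents in the 3 morphs, in the order of list length. Of the 51919 such regions, H3K27ac was listed at 9.09% in surface, 17.9% in Pachón and 33.7% in Tinaja, and H3K4me3 at 24.6%, 35.7% and 66.9%. With lists cut to equal length by width, H3K27ac stood at 9.10% in surface (95% interval 8.85 to 9.35), 15.0% in Pachón (14.7 to 15.4) and 22.4% in Tinaja (22.0 to 22.7). H3K4me3 stood at 24.7%, 33.2% and 37.3%. That cut keeps the wider cave peaks and leaves surface whole, so it does not remove every effect of list length. Nor can surface against cave be told apart from library number for the active marks. H3K27ac peaks without H3K4me3, merged across morphs, gave 90213 regions, of which 16245 (18.01%) were in all 3 morphs, 21250 in Pachón alone, 15419 in Tinaja alone and 11432 in surface alone.

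H3K4me3 and H3K27ac regions of the cave pair lay on surface H3K27me3 more often than regions of all 3 morphs. With lists of equal length the ratio of shares was 1.75 for H3K4me3 and 2.69 for H3K27ac. That cut kept the wider cave peaks and left the surface lists of these marks whole. It raised the share in the cave pair from 50.5% to 63.5% for H3K4me3 and from 28.1% to 37.1% for H3K27ac. The regions of all 3 morphs moved little, to 36.3% and 13.8%. The ratio therefore does not decide whether longer cave lists contribute. Region width decides nothing, since narrower regions, as those of the cave pair were, meet fewer peaks by chance and matching width had to raise the H3K4me3 ratio, to 1.85. For H3K4me3 the share in the cave pair exceeded that in Tinaja alone by 16.2 percentage points and that in Pachón alone by 26.5. Within bins of width the excess was 5.14 and 15.5 points. By the surface list, which both other pairs include, surface and Pachón (33.3%) also exceeded surface alone (28.4%) and Pachón alone (24.0%). Surface and Tinaja (29.4%) stayed below Tinaja alone (34.3%). By H3K27me3 of the morph left out, surface and Pachón (17.7%) stayed below Pachón alone (23.3%). Surface and Tinaja (27.3%) likewise stayed below Tinaja alone (35.5%). By that measure only the cave pair exceeded both of its single morphs. The other pairs were not compared within bins of width or with equal lists. The excess therefore does not decide whether something shared by the caves contributes, be it the fish or the library numbers that separate them from surface. For H3K27ac the difference was -7.10 points from Tinaja alone and 13.8 from Pachón alone (-15.6 and 5.70 within bins of width), so a shared cave difference, a library effect and one particular to Tinaja all remain open.

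H3K27ac and H3K27me3 differed between cave and surface in the same direction more often than independent marks would, with an odds ratio of 8.59. Unplaced scaffolds are argued against by an odds ratio of 6.07 on placed chromosomes. The higher odds ratio of the other 2 splits was 1.35, which leaves open something particular to cave against surface, be it the fish or the libraries. The H3K27me3 libraries of all morphs shared a library number. For these marks that number thus separates surface from cave in H3K27ac alone. Sequence missing from or unmapped in the cave libraries may contribute: regions with both marks in surface alone had no cave peak of any mark within 5 kb 2.66 times as often as H3K27ac regions of surface alone that met no H3K27me3 (15.8% of 285 against 5.93% of 6930). Without regions of surface alone that had no cave peak within 5 kb, the odds ratio was 7.21. This argues against sequence missing for 5 kb or more on both sides of a region as the whole cause. Missing stretches that end within 5 kb of a region remain untested.

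The widest H3K4me3 domains coincided with the widest H3K27me3 domains 80 times over the 3 morphs, and in 52 of these a pair of domains had both ends within 500 bp of each other. Of the 80, 30% lay on placed chromosomes, but loci recurred between morphs, and of the 49 distinct loci 24.5% were placed (95% interval 13.3 to 38.9). Among the distinct loci of the widest H3K4me3 domains that did not coincide, 57.8% of 161 were placed (49.7 to 65.5). Most coincidences thus lay outside the placed chromosomes. An unplaced scaffold is a matter of the assembly, so position does not decide whether these were bivalent domains. Repeated sequence collapsed in the assembly, which would gather reads in any library, was not tested, as no genome of this build was used here. H3K27ac was rarely wide at the same places, as 1, 1 and 3 of its 100 widest domains met one of H3K27me3 in surface, Pachón and Tinaja.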
